A study of Drosophila melanogaster with 36 samples.

How the data were processed

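Transcript levels in Drosophila melanogaster embryos were measured on Affymetrix one-colour expression arrays. Per the labels' protocols, total RNA was extracted with TRIzol, turned into double-stranded cDNA with the one-cycle protocol, transcribed into biotin-labelled cRNA, fragmented and hybridised. The series holds 36 arrays, 18 of embryos at 5 h and 18 at 8 h. Per the labels, the arrays belong to 9 isogenic lines with 2 RNA samples for each line and time. A line is named here by its 5 h array titles without the sample letter, from Drosophila_17 to Drosophila_145. An isogenic line is a fly stock bred until its members carry nearly the same genome. The title of 1 array at 5 h names no line, so line comparisons used the other 35 arrays, and line Drosophila_17 had 1 array at 5 h. Nothing in the labels says whether the 2 RNA samples of a line came from separate embryo collections, so p-values for lines measure only the spread between these RNA samples, which may be technical.

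The values deposited by the authors are intensities on a linear scale, with 18952 probe sets on each array. The software that turned scans into intensities, and any scaling it applied, are not given in the sources used here. The lowest deposited intensity was 0.0049 and the highest of a non-control probe set was 4215.6. The 183 control probe sets were left out, which left 18769. All columns of per-sample values were used. The deposited intensities were not brought to a common brightness: the 90th percentile ranged from 4.1 to 32.7 and the total from 46261 to 309710. The cre spike-in ranged from 8004 to 12780 and the bioB spike-in from 409.8 to 1445. Signal over background was judged with 49 control probe sets taken by their names as negative controls, which no source used here states, and whose 99th percentile was the limit on each array. Between 3152 and 8128 probe sets lay above it, and 6194 did so on at least 18 of the 36 arrays and are called measured here. The number of arrays limits the precision.

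The plan, fixed before the data were examined, kept the deposited scale if the arrays' medians spanned at most 0.5 on the log2 scale, and otherwise called for quantile normalisation. The medians of log2 deposited intensity spanned 0.89, so intensities were quantile normalised over non-control probe sets and transformed as log2(intensity + 16). With the pseudocount of 16 added first, the medians spanned only 0.062, so the plan could also be read as keeping the deposited scale, which is given as an alternative. Fold changes are on the log2(intensity + 16) scale and understate the change of dim probe sets. After normalisation 91.3% of values lay under the pseudocount.

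Fits used limma 3.58.1 in R 4.3.3 with a trended prior variance and Benjamini-Hochberg adjustment over 18769 probe sets, at an adjusted p of 0.05. For 8 h against 5 h, arrays were averaged to 18 means of line and time, and times were compared with the line as a block, so that the 9 lines are the replicates (8 residual degrees of freedom). For the lines, a mean was fitted for each line and time (17 residual degrees of freedom), with moderated F tests among lines at 5 h, at 8 h, over both times, and for the change from 5 h to 8 h, and contrasts of each line against the other 8. The among-line share of variance is the intraclass correlation from a one-way analysis of variance estimate, set against 100 permutations of line labels. Data were simulated with the same signals and with the spread between RNA samples. There 100 of 100 probe sets with a change of 0.5 and 98 of 100 with a line SD of 0.5 were called. Of 18569 unchanged probe sets 11 and 12 were called for time and for lines. No line-by-time differences were simulated there. The test for time has the spread of change between lines as its error, so the simulated rate for a change of 0.5 is too high where lines differ in their change.

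Probe sets were named from the platform annotation, with symbols updated through the gene number to the RefSeq table of Release 6 plus ISO1 MT. There were 13647 probe sets with 1 symbol, 402 with several and 4720 unnamed here, and 13544 of the first were matched to the table. A gene was represented by its probe set of highest mean, which gave 11982 genes. The 33 gene lists were written before the data were examined. Their change with time was tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Their variation among lines was tested with the median log10 F of a list. It was set against 10000 random lists of the same size, matched on mean signal in 20 bins. This is called a permutation test here, but it draws genes and does not permute line labels, and its smallest p is 1e-04. It takes list members as independent, so its p can be too small for lists whose members vary together. The developmental score of an array is the mean over the 200 probe sets that rose most minus the mean over the 200 that fell most from 5 h to 8 h in the other lines.

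Genes named for time were the 12 largest rises and the 12 largest falls past the threshold that moved the same way in 9 of 9 lines, with a symbol other than a CG or CR number, and up to 4 called members of each list. Genes named for lines were the 15 with the largest range of line means among those called at both times, with at most 5 CG numbers, 1 gene per line, the 6 lowest p for the change that differs among lines, and up to 3 members of each list that varied among lines. The rule was set before the data were examined, and other genes are marked where they appear.

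At 5 h the bioB spike-in was lower in sample 2 than in sample 1 in 8 of 8 lines with both arrays, and at 8 h in 5 of 9. Alternatives covered other scalings, pseudocounts, filters, variance models, array weights, the placement of the array of unnamed line, the sample number as a block, array brightness and developmental score as covariates, and leaving out each array or line.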

Results

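Embryos of 9 isogenic Drosophila melanogaster lines were profiled at 5 h and 8 h to ask how transcript levels change over early development and how far they vary between genotypes. The series holds 36 arrays, with 2 RNA samples for each line and time, and 1 array at 5 h whose line is not named. Total intensity per array ranged from 68984 to 309710 at 5 h and from 46261 to 266525 at 8 h. Between 3152 and 8128 of 18769 probe sets lay above the negative-control limit. Pairs of arrays of the same line and time correlated across 6194 measured probe sets with a median r of 0.955, and arrays of different lines at the same time with a median r of 0.903; probe sets are not independent replicates. Intensities below are quantile normalised, as mean ± SD over the 9 lines, and changes are given as log2 ± SE.

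Among genes with symbols other than CG or CR numbers that moved the same way in 9 of 9 lines, the largest falls from 5 h to 8 h included genes of cellularisation, when membranes enclose the nuclei of the syncytial embryo. Z600, a zygotic inhibitor of mitosis also known as frühstart, fell from 123 ± 95 to 3.55 ± 5.02 (SD, n = 9), a change of -2.44 ± 0.25 with adjusted p = 5.5e-06. The membrane-growth gene slam fell from 177 ± 142 to 17.2 ± 12 (SD, n = 9; -2.22 ± 0.24, adjusted p = 1.3e-05). The lipid-droplet transport gene halo changed by -2.02 ± 0.2, Sry-alpha by -1.49 ± 0.17 and the insulator gene Elba3 by -1.11 ± 0.13. SNCF, bard, Bro and the cathepsin gene CtsK1 were also among the 12 largest falls, with changes between -2.15 and -0.87. The remaining places were taken by proteasome core genes, with Prosalpha2 falling from 148 ± 48.3 to 60.2 ± 23.6 (SD, n = 9; -1.12 ± 0.17), Prosbeta4 by 0.99 and Prosalpha7 by 0.87 on the log2 scale.

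Among the same genes the largest rise was that of ImpL2, a secreted insulin-binding protein and ecdysone-inducible gene, from 20.1 ± 12.1 to 113 ± 59.5 (SD, n = 9; 1.76 ± 0.16, adjusted p = 1.5e-06). The tracheal and salivary gland regulator rib rose from 58.9 ± 32.1 to 200 ± 105 (SD, n = 9; 1.48 ± 0.16, adjusted p = 1.4e-05). Nplp2 and the odorant-binding protein gene Obp99a each rose by 1.40, and the neural cell-surface gene Ama by 1.31 ± 0.14. Of the Bearded family, which tempers Notch signalling, Tom rose by 1.25 ± 0.16, Brd by 1.15 ± 0.16, E(spl)malpha-BFM by 0.96 ± 0.11 and BobA by 0.88 ± 0.17. The RNA-binding gene ps, Drat and the kinase gene Hipk rose by 1.09, 0.94 and 0.91.

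**Figure D1:**
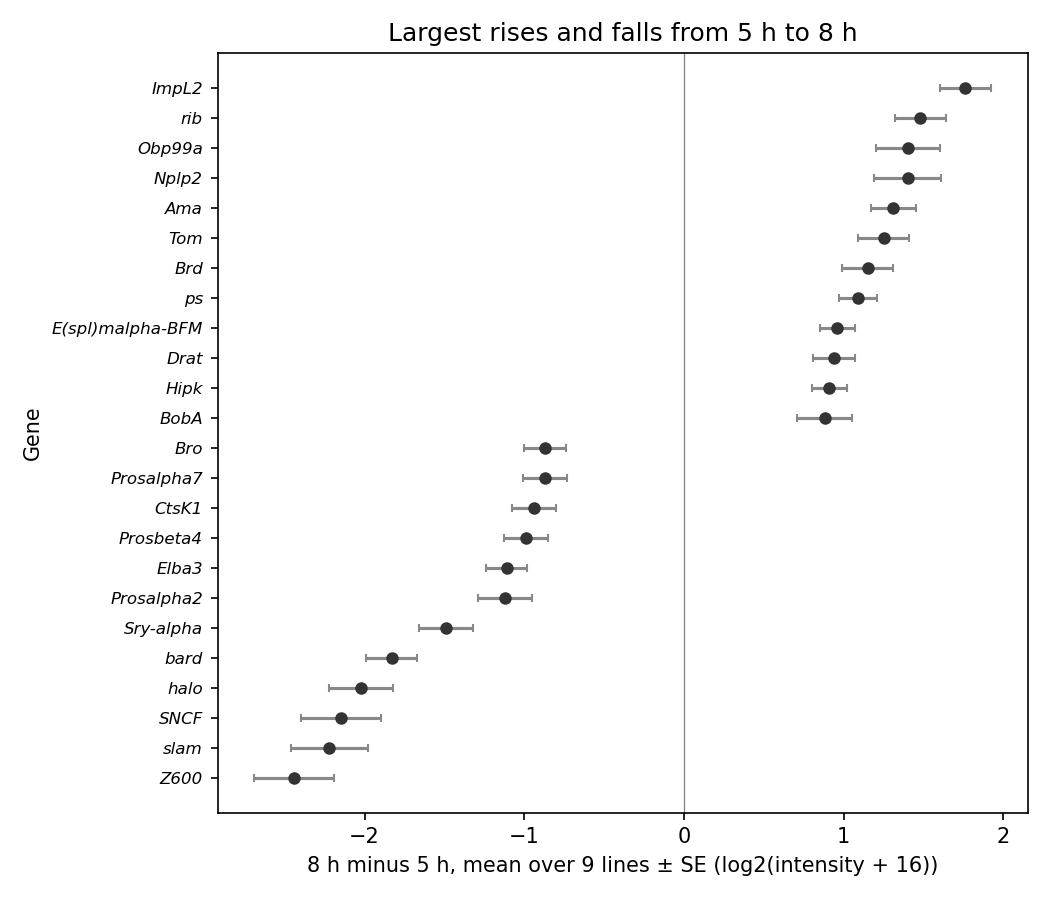
Change from 5 h to 8 h of the 12 genes with the largest rises and the 12 with the largest falls, as the mean over 9 lines on the log2(intensity + 16) scale (x axis), with bars of 1 SE. Changes run from -2.44 for Z600 to 1.76 for ImpL2.

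In all, 1411 probe sets differed between 8 h and 5 h, 723 rising and 688 falling, and 700 of them moved the same way in 9 of 9 lines; 33 changed at least 2-fold. The split depended on the scaling. It was 328 rising against 2948 falling on the deposited scale, 374 against 2509 with arrays centred on their medians and 1349 against 539 with arrays scaled to a common 90th percentile. On the deposited scale 986 of the 1411 calls were kept in the same direction and 0 were called in the opposite direction. Genes that lost the call there could still change sign, as wun2 and RpL28 did. For 8 h against 5 h, 2594 probe sets were called with the array as the unit, and 939 when array brightness was added to that fit as a covariate. On line means, 918 were called without line Drosophila_83. Some named genes were near background at 1 time. At 5 h gsb, wor, Prm, Ppn, skl, stv, Ugt35D1 and GstE3 lay above the negative-control limit on 4 to 8 of 18 arrays, and at 8 h Z600, bard, Bro, Elba3, tll, eve, zen, tld, scw and egr did on 0 to 8. The falls of these genes end near background.

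Of 33 gene lists, 12 shifted upward and 6 downward against other genes with the preset correlation of camera, and 0 did with an estimated one (10 at an unadjusted p under 0.05). Of 14 Notch target and Bearded family genes 12 rose and 0 fell (12 adjusted over the list alone; camera adjusted p = 3.4e-15, and adjusted p = 0.1 with an estimated correlation). E(spl)m5-HLH, a Notch-induced repressor gene also placed on the early zygotic list, rose from 6.53 ± 4.31 to 29.4 ± 16.8 (SD, n = 9; 0.93 ± 0.14), while E(spl)m6-BFM stood at -0.01 ± 0.02 and neur at -0.04 ± 0.08, neither called. Of 11 segment polarity genes 5 rose and none fell (7 adjusted over the list alone; adjusted p = 2e-06, and adjusted p = 0.11 with an estimated correlation). en, the posterior compartment selector, rose by 0.75 ± 0.12, the Hedgehog effector gene ci by 0.63 ± 0.12, gsb by 0.33 and nkd by 0.29. Of 4 Hox genes 1, Antp, rose, by 0.43 ± 0.08 (2 adjusted over the list alone), and the list was not called (adjusted p = 0.11).

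Of 18 neuroblast genes 8 rose (11 adjusted over the list alone; adjusted p = 1.8e-05, and adjusted p = 0.16 with an estimated correlation), among them pdm2 by 0.50, pros by 0.42, SoxN by 0.42 and wor by 0.38. Of 17 neuron and glia genes 7 rose (7 adjusted over the list alone; adjusted p = 9.4e-05, and adjusted p = 0.15 with an estimated correlation), including the axon guidance gene comm by 0.67 ± 0.09, the neuronal RNA-binding gene elav by 0.48, the glial regulator gcm by 0.38 and the Slit receptor gene robo1 by 0.33. Of 13 mesoderm and myogenic regulators 6 rose (8 adjusted over the list alone; adjusted p = 3.5e-06, and adjusted p = 0.11 with an estimated correlation), with lmd at 0.31, eya at 0.20 and the visceral mesoderm genes bin and bap each at 0.17. Of the 13, 4 were measured. lmd, eya, bin and bap lay above the negative-control limit on 4, 9, 2 and 5 of 18 arrays at 5 h and on 14, 14, 8 and 13 at 8 h. Of 12 muscle structural genes 4 rose (9 adjusted over the list alone; adjusted p = 3.6e-06, and adjusted p = 0.28 with an estimated correlation). These were Act87E by 0.84 ± 0.15, Mlc1 by 0.74 ± 0.2, Mlp60A by 0.54 and Prm by 0.30, rising in 8, 7, 6 and 7 of 9 lines. The muscle list mean rose most in lines Drosophila_58 (4.68 to 5.2), Drosophila_83 (4.49 to 5.46), Drosophila_89 (4.46 to 5.34) and Drosophila_134 (4.57 to 5.51). It went from 4.29 to 4.5 in line Drosophila_17, 4.23 to 4.26 in line Drosophila_128 and 4.24 to 4.32 in line Drosophila_145. It fell from 4.47 to 4.28 in line Drosophila_23 and from 4.66 to 4.51 in line Drosophila_75. Of 17 haemocyte and fat body genes 9 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 3.7e-07, and adjusted p = 0.11 with an estimated correlation). The laminin genes rose, LanA by 0.73 ± 0.11, LanB2 by 0.61 ± 0.1 and LanB1 by 0.56 ± 0.09, as did the matrix gene Ppn by 0.40.

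Of 10 tracheal genes 4 rose (7 adjusted over the list alone; adjusted p = 3.5e-06, and adjusted p = 0.1 with an estimated correlation), with peb at 0.66 ± 0.09, verm at 0.31 and vvl at 0.15 after rib. Of the 10, 5 were measured. verm and vvl lay above the limit on 4 of 18 arrays at 5 h and on 8 and 11 at 8 h. Of 10 endoderm and gut genes 5 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.12 with an estimated correlation). drm, bowl and srp rose by 0.31, 0.27 and 0.21, and the posterior patterning gene cad fell by 0.45. Of 10 amnioserosa genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.0043, and adjusted p = 0.16 with an estimated correlation). Ance rose by 0.64 ± 0.09, ush by 0.38 and zen, a dorsal homeobox gene, fell by 0.63 ± 0.08. Gasp, at 0.37 ± 0.1, was the 1 called member of 15 epidermis and cuticle genes (2 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.37 with an estimated correlation).

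Of 17 maternal transcripts 9 fell and none rose (11 adjusted over the list alone; adjusted p = 7.4e-08, and adjusted p = 0.1 with an estimated correlation). gnu, a regulator of the early nuclear cycles, fell from 26.1 ± 13.6 to 11.3 ± 10.9 (SD, n = 9; -0.65 ± 0.1), the germ plasm organiser osk fell by 0.55 ± 0.13 and swa fell by 0.45, while bcd stood at -0.08 ± 0.15 and was not called. The thioredoxin gene dhd fell by 0.62 ± 0.14, but stood at 0.18 with array brightness as a covariate. Of 10 cellularisation and early zygotic genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 7.4e-08, and adjusted p = 0.1 with an estimated correlation). Of 9 germ cell genes 4 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.043, and adjusted p = 0.16 with an estimated correlation), and without lines Drosophila_75 and Drosophila_89 the list was not called (adjusted p = 0.083). gcl, aub and zpg fell by 0.40, 0.34 and 0.20. wun2 rose by 0.24 but stood at -0.06 on the deposited scale and -0.04 with centred medians. Of 11 gap and terminal genes tll and gt fell by 0.50 and 0.30 and ems rose by 0.33 (1 risen and 4 fallen adjusted over the list alone); the list was not called (adjusted p = 0.25). Of 8 pair-rule genes ftz, eve and prd fell by 0.37, 0.35 and 0.28 and Ten-m rose by 0.38 (1 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.093). At the preset correlation of camera both lists were called downward on the deposited scale (adjusted p = 0.038 and 0.018) and with centred medians (adjusted p = 0.029 and 0.016). With an estimated correlation, fitted on quantile normalised values alone, camera gave adjusted p = 0.65 and 0.53. The pair-rule list was also called downward at a common 90th percentile (adjusted p = 0.011) and without lines Drosophila_75 and Drosophila_89 (adjusted p = 0.021), so quantile normalisation with all lines was the exception among these settings. Of 12 dorsal-ventral patterning genes 3 rose and 3 fell (6 and 5 adjusted over the list alone), including tld and scw, which fell by 0.19 and 0.15; the list had a median of 0.06, a mean of -0.02 and adjusted p = 0.9.

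Of 69 mitochondrial ribosomal protein genes 19 fell and 1 rose (28 and 1 adjusted over the list alone; adjusted p = 3.3e-09, and adjusted p = 0.11 with an estimated correlation). Of 72 respiratory chain genes 17 fell and 0 rose (20 adjusted over the list alone; adjusted p = 4.5e-08, and adjusted p = 0.13 with an estimated correlation). mRpS21, mRpL33, mRpL14 and mRpL13 fell by 0.44, 0.37, 0.33 and 0.31, and the ATP synthase genes ATPsynE, ATPsynbeta, ATPsynB and ATPsyndelta by 0.57, 0.55, 0.49 and 0.48. Eno and Gapdh1 fell by 0.55 and 0.47 among 9 glycolysis genes (3 fallen adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.27 with an estimated correlation). Of 41 ribosomal protein genes 8 rose (9 risen and 2 fallen adjusted over the list alone; adjusted p = 0.0029, and adjusted p = 0.28 with an estimated correlation), among them RpL27 by 0.52 ± 0.1, RpL37A by 0.30, RpL28 by 0.28 and RpL37-1 by 0.26. The direction of this list turned with the scaling. Its median was 0.07 here, -0.24 on the deposited scale and -0.19 with centred medians, where it was not called, and 0.27 with arrays scaled to a common 90th percentile (adjusted p = 1.2e-09). RpL37A, RpL28 and RpL37-1 stood at -0.01, -0.06 and -0.15 on the deposited scale. Of 5 heat shock genes Hsp68 and stv rose by 0.64 ± 0.1 and 0.22 (3 risen and 1 fallen adjusted over the list alone). The heat shock list had adjusted p = 0.055 by camera, and adjusted p = 0.45 with an estimated correlation. Without lines Drosophila_75 and Drosophila_89 it had adjusted p = 0.019 at the preset correlation. Of 150 detoxification genes 6 rose and 6 fell (7 and 6 adjusted over the list alone; adjusted p = 0.47); Ugt35D1 and GstE3 rose by 0.45 and 0.39, and GstT1 and GstT3 fell by 0.51 and 0.34. Of 6 apoptosis genes skl rose by 0.17 and egr fell by 0.16 (1 and 1 adjusted over the list alone; adjusted p = 0.78). Of 11 ecdysone response genes 1, ImpL2, rose (1 adjusted over the list alone; adjusted p = 0.48). Of 15 cell cycle genes 0 were called by limma (3 at an unadjusted p under 0.05, 0 adjusted over the list alone). The cell cycle list had adjusted p = 0.83 by camera, and adjusted p = 0.91 with an estimated correlation. At the preset correlation it was called downward on the deposited scale (median -0.34, adjusted p = 0.005). Limma called 0 of 8 ecdysteroid synthesis, 8 antimicrobial peptide and PGRP, 15 eggshell and yolk, 22 adult midgut protease, 8 dosage compensation and sex determination and 112 chemoreceptor genes (0 adjusted over the list alone in each). At an unadjusted p under 0.05 there were 0, 1, 0, 4, 1 and 7 of them, and the list adjusted p were 0.52, 0.45, 0.85, 0.5, 0.75 and 0.85. On the deposited scale camera called the detoxification, protease and chemoreceptor lists upward against other genes (adjusted p = 0.0068, 0.018 and 0.0037). Their medians there were 0, 0.01 and 0, while 2948 probe sets fell and 328 rose, so this does not show that these genes rose. Of these lists 29 of 150, 0 of 22 and 0 of 112 genes were measured.

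Among genes with 1 symbol that were called for lines at both times, the widest difference was in a maternal transcript. The thioredoxin gene dhd spanned 3.48 log2 units, from 4.57 in line Drosophila_134 to 8.04 in line Drosophila_75, or intensities of 9.97 and 279 at 5 h (adjusted p = 0.00013). Hsp26 and the glycolytic gene Eno were also highest in lines Drosophila_75 and Drosophila_89 and lowest in line Drosophila_134 at spans of 2.21 and 2.26. Array brightness also differed, with total intensities of 212329 to 266525 in line Drosophila_75, 261232 and 309710 in line Drosophila_89 at 5 h (121704 and 140785 at 8 h) and 46261 to 110030 in line Drosophila_134. Other lines overlapped these ranges, line Drosophila_58 reaching 234801 at 5 h and line Drosophila_145 running from 68984 to 134588. For lines over both times, dhd, Hsp26 and Eno were still called with brightness as a covariate. The slope on brightness rests only on differences between RNA samples of the same line and time, so this does not exclude brightness. Other genes ran the other way. The gene mira, which segregates fate determinants in neuroblasts, was lowest in line Drosophila_75 (4.56) and line Drosophila_89 (5.22) and highest in line Drosophila_128 (6.96; adjusted p = 1.8e-09). Tom was 5.50 in line Drosophila_75 against 7.84 in line Drosophila_134 (adjusted p = 4.4e-07). CG13427 and CG4440 were likewise lowest in line Drosophila_75 and next lowest in line Drosophila_89, with spans of 3.45 and 3.02. In all, 3661 probe sets differed for lines over both times, 483 of them with line means spanning at least 1 log2 unit.

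Some genes set 1 line apart. betaTub60D, a tubulin of differentiating cells, reached 6.91 in line Drosophila_58 and 5.80 in line Drosophila_83 against 4.80 or less in the other 7 lines. Obp99a, Nplp2 and CG9184 were also highest in line Drosophila_58 and next highest in line Drosophila_83. Of these genes betaTub60D, Obp99a and Nplp2 also rose from 5 h to 8 h, and CG9184 was not called for time. CG43085 reached 6.51 in line Drosophila_89 (96.7 at 5 h) and at most 4.62 elsewhere (adjusted p = 6.9e-20). Oda, which encodes ornithine decarboxylase antizyme, was 4.45 in line Drosophila_128 against at least 6.01 elsewhere (adjusted p = 7e-12). Cul1, a ubiquitin ligase scaffold, was 4.42 there against at least 5.74 (adjusted p = 1.9e-11). GstD1, a detoxification enzyme, was lowest in line Drosophila_83 (4.08), near the floor, and highest in lines Drosophila_128 and Drosophila_75 (6.83 and 6.79). Against the other 8 lines, among genes with symbols other than CG or CR numbers that passed the test for that line, the one that departed most was Obp99a in line Drosophila_17 (-1.23), the kinase gene dco in line Drosophila_23 (-1.30), betaTub60D in line Drosophila_58 (2.11), dhd in lines Drosophila_75 and Drosophila_134 (2.03 and -1.88), GstD1 in line Drosophila_83 (-1.65), the cuticle gene TwdlL in line Drosophila_89 (1.59), Oda in line Drosophila_128 (-1.94) and Tnpo, a nuclear import gene, in line Drosophila_145 (1.42). TwdlL, above the negative-control limit on fewer than 18 of the 36 arrays, was also high in line Drosophila_134, at 6.29 against 6.18 in line Drosophila_89. Lines Drosophila_75, Drosophila_58 and Drosophila_134 departed in 1617, 1538 and 1260 probe sets and lines Drosophila_83, Drosophila_17 and Drosophila_23 in 149, 176 and 206. With the array of unnamed line placed in line Drosophila_17, its count was 555. On the deposited scale the counts of lines Drosophila_75, Drosophila_58 and Drosophila_134 were 4909, 2116 and 3157, and those of lines Drosophila_83, Drosophila_17 and Drosophila_23 were 45, 35 and 95. Line Drosophila_89 had 600 here and 2507 on the deposited scale, above line Drosophila_58. With centred medians these lines had 1873 and 1350.

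**Figure D2:**
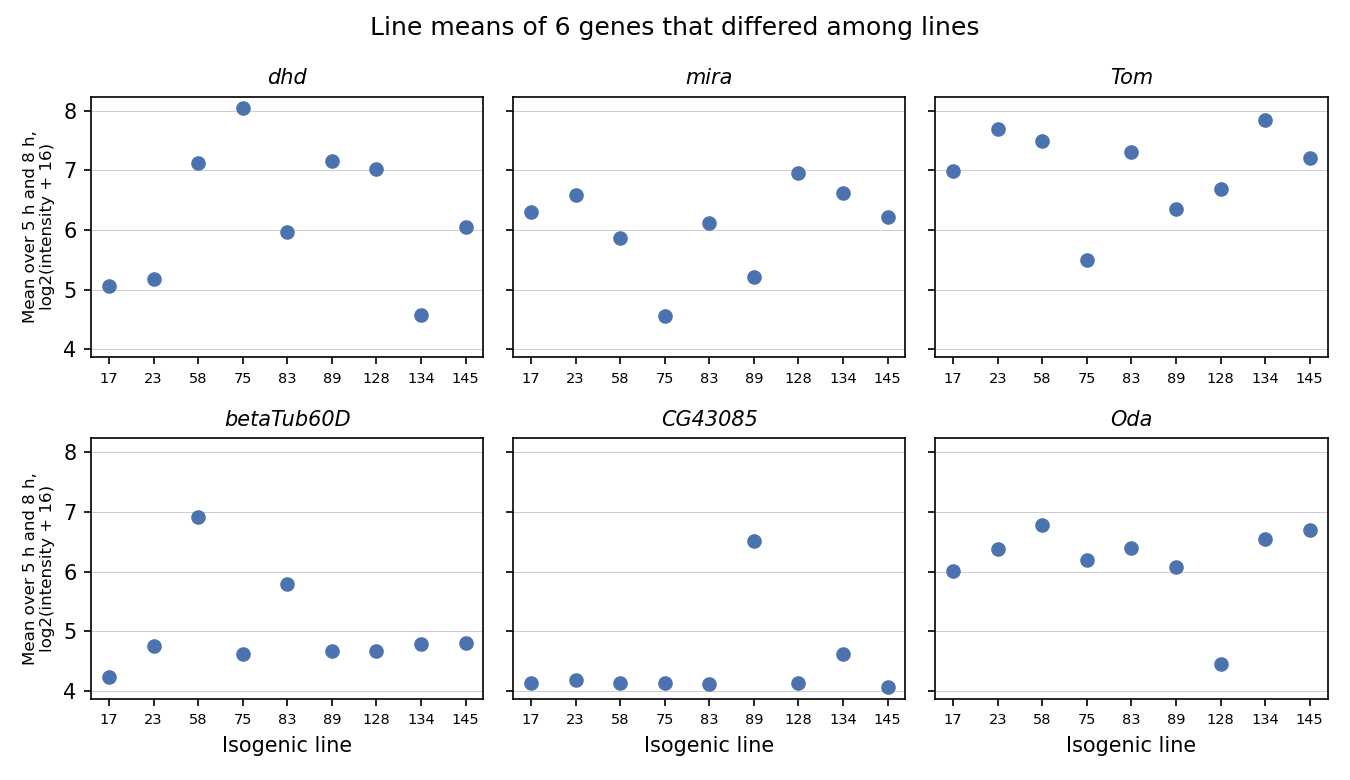
Mean over both times on the log2(intensity + 16) scale (y axis) of 6 genes in each of 9 isogenic lines (x axis, by number), each point a line mean. dhd spans 4.57 to 8.04, mira and Tom are lowest in line Drosophila_75, betaTub60D is highest in line Drosophila_58, CG43085 in line Drosophila_89, and Oda is lowest in line Drosophila_128.

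The lines differed in 1399 probe sets at 5 h and 3447 at 8 h, 964 being called at both times. The median among-line share of variance was 13.8% at 5 h and 12.8% at 8 h, against at most 6.17% and 3.2% in 100 permutations of line labels. It was 47.5% and 43.7% over the 6194 measured probe sets. The count of probe sets called for lines at 5 h was 4418 on the deposited scale, 3191 with centred medians, 2267 with array weights, 486 with array brightness as a covariate and 509 without lines Drosophila_75 and Drosophila_89. The count for lines at 8 h was 2272 without those lines and 2243 with the developmental score as a covariate. The count for lines over both times was 6259 on the deposited scale, 2075 without lines Drosophila_75 and Drosophila_89 and 2323 with brightness as a covariate. The share at 5 h was 22.3% without the first 5 h array of line Drosophila_145.

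Of the 33 lists, 11 varied more among lines than random lists of the same signal and 2 varied less. Each was called by the permutation test with 10000 draws of genes (adjusted p from 0.0022 to 0.013 for the first, and 0.026 and 0.0088 for the others). That test takes list members as independent, so these p can be too small. In the maternal list 16 of 17 genes differed among lines (16 adjusted over the list alone), and fs(1)N and gnu were highest in line Drosophila_75 and next highest in line Drosophila_89, while plu was highest in line Drosophila_17 (5.23) and lowest in line Drosophila_58 (4.16). All 8 pair-rule genes differed (8 adjusted over the list alone), opa, hry and prd being lowest in line Drosophila_75. In the gap and terminal list 8 of 11 differed (10 adjusted over the list alone), with kni, hkb and ems lowest in line Drosophila_75. In the cellularisation list 8 of 10 differed (8 adjusted over the list alone), where slam spanned 5.26 in line Drosophila_58 to 7.14 in line Drosophila_145 and Bro and Sry-alpha were also high in lines Drosophila_134 and Drosophila_23. twi, sna and zen, of the dorsal-ventral list with 7 of 12 called (9 adjusted over the list alone), were highest in line Drosophila_134, and D and pros, of the neuroblast list with 12 of 18 called (15 adjusted over the list alone), were lowest in line Drosophila_75. Of the Notch target and Bearded list 13 of 14 differed (13 adjusted over the list alone), Brd spanning 4.65 in line Drosophila_75 to 6.72 in line Drosophila_128. These comparisons are over both times. sna was not called for lines at 5 h alone (F test, adjusted p = 0.31), and zen and Bro were not at 8 h alone (F test, adjusted p = 0.42 and 0.95).

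Several genes were highest in line Drosophila_58, the line of highest 5 h developmental score (-0.301). They were LanA at 6.22, LanB2 at 5.65 and Ppn at 5.44 of the haemocyte list (13 of 17 called, 13 adjusted over the list alone), Ance at 5.76 of the amnioserosa list (7 of 10 called, 8 adjusted over the list alone), E(spl)m3-HLH at 5.07 of the Notch target list, and grh and mwh at 4.95 and 4.53 of the epidermis list (8 of 15 called, 11 adjusted over the list alone). These values are means over both times, and at 5 h alone Ppn, grh and mwh were not called for lines (F test, adjusted p = 0.071, 0.098 and 0.86). LanA, LanB2, Ppn, Ance and E(spl)m3-HLH also rose from 5 h to 8 h, while grh and mwh were not called for time. Among measured probe sets, 909 of the 1261 called for time were also called for lines over both times, against 647 expected if the calls were unrelated. These values cannot tell embryo age from line. rib, peb and salm of the tracheal list (6 of 10 called, 8 adjusted over the list alone) were lowest in line Drosophila_75. peb was not called at 5 h alone (F test, adjusted p = 0.11). The variation of the tracheal list had an adjusted p of 0.0022 in the permutation test. Mitochondrial ribosomal protein genes (23 of 69 called, 35 adjusted over the list alone) and respiratory chain genes (28 of 72 called, 32 adjusted over the list alone) varied less than their random lists, although ND-39 was low in line Drosophila_58 (4.23). With the developmental score as a covariate 8 lists were called, and the maternal, dorsal-ventral, Notch target, tracheal and both mitochondrial lists were not. With array brightness as a covariate the gap and terminal, dorsal-ventral and amnioserosa lists were not called (adjusted p = 0.77, 0.2 and 0.16 in the permutation test), while the muscle, neuron and glia, and detoxification lists were (adjusted p = 0.011, 0.033 and 0.02). On the deposited scale 7 lists were called, and of the 11 more variable lists the maternal and epidermis lists alone were among them. Without lines Drosophila_75 and Drosophila_89, kni, ems, Brd, peb and salm were no longer called for lines. The heat shock list, with 4 of 5 genes called, had adjusted p = 0.052 in the permutation test and 0.025 on the deposited scale.

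The measured change of several genes of cellularisation, among them slam, differed among the 9 lines. The change from 5 h to 8 h differed among lines for 257 probe sets, and 4 of the 6 genes of lowest p fell most in line Drosophila_134 and least in line Drosophila_75 or line Drosophila_89. Z600 changed by -3.99 in line Drosophila_134 but by -0.72 in line Drosophila_75 and -0.77 in line Drosophila_89 (adjusted p = 7.3e-06), and its 5 h intensity was 259, 10.7 and 14.4 in those lines. slam changed by -4.15, -0.84 and -0.55 (adjusted p = 9e-06), bard by -3.08, -1.01 and -0.75, and CG34214 by -3.38, -0.85 and -0.37. Bro (adjusted p = 6.4e-09) changed by -1.75 in line Drosophila_145 and -1.62 in line Drosophila_134 and by -0.22 in lines Drosophila_58 and Drosophila_75, and CG14014 by -1.70 in line Drosophila_17 and -0.29 in line Drosophila_75. At 8 h Bro, CG34214, Z600 and bard lay at 14.8 or less in every line. Bro, Z600 and bard were above the negative-control limit there on 1, 3 and 6 of 18 arrays, so their falls end in a bound and are limited by the 5 h level. The count for this line by time interaction moved with single arrays, from 144 without the first 5 h sample of line Drosophila_75 to 453 without the first 8 h sample of line Drosophila_128, and was 129 with a pseudocount of 1, under which CG14014 was no longer called (adjusted p = 0.17).

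The developmental score, a summary of how far an array had moved along the change seen in the other lines, averaged -1 ± 0.308 at 5 h and 0.201 ± 0.604 at 8 h (SD, n = 9 lines). At 8 h it ran from -0.775 in line Drosophila_75 to 1.12 in line Drosophila_134, and at 5 h line Drosophila_58 stood at -0.301 while the other lines lay between -1.43 and -0.895. The changes of line Drosophila_75 had a slope of 0.242 on the mean change of the other lines, across probe sets called without it, and line Drosophila_134 a slope of 1.57. Brightness also differed at 8 h, with total intensities of 266525 and 212329 in line Drosophila_75 and 74632 and 46261 in line Drosophila_134. Line Drosophila_58, with an 8 h score of 0.873, had 190386 and 169245. Whether brightness moved the score was not tested.

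**Figure D3:**
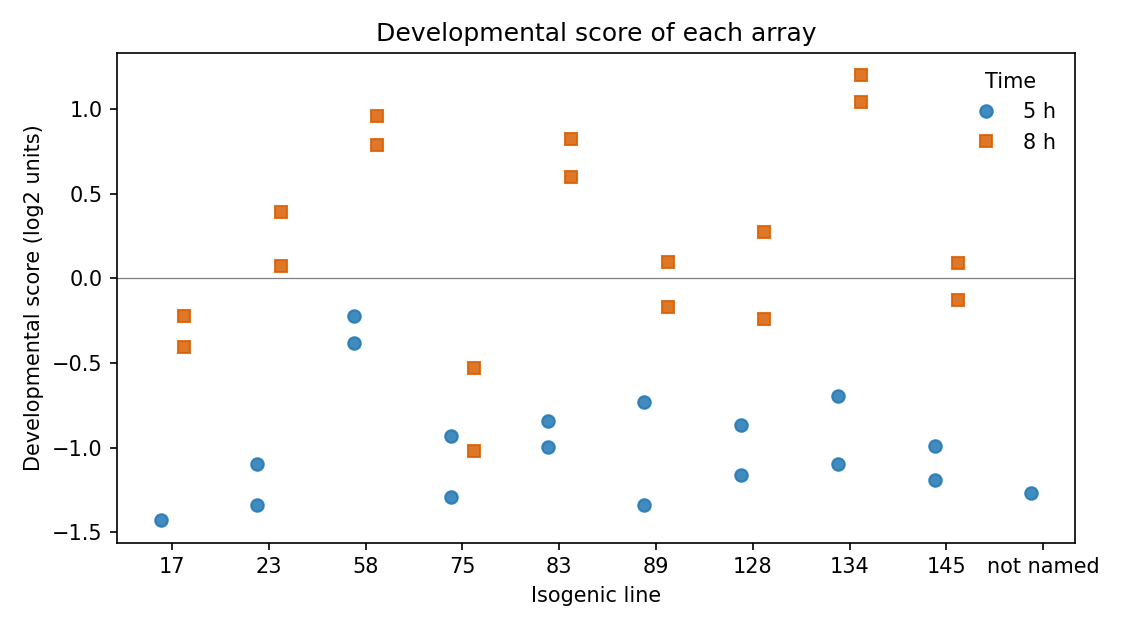
Developmental score of each array in log2 units (y axis) by number of the isogenic line (x axis), at 5 h (circles) and 8 h (squares), with the array of unnamed line at the right. The 8 h arrays of line Drosophila_75 lie among the 5 h arrays of other lines, and line Drosophila_58 has the highest 5 h score.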

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

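The tests of embryo age, eggs that did not develop and exchanged arrays were chosen after the results they bear on were seen, and the brightness covariate after seeing the data. Among 156 sets of 9 line values, 18 had a highest or lowest line set apart by a large gap (Dixon's ratio at the 95% level), and chance alone flags about 1 in 20, a rate that does not hold for the line means, whose genes were chosen for differing among lines. Line Drosophila_58 stood apart for line means of CG9184 (gap ratio 0.688), E(spl)m3-HLH (0.526), mwh (0.626), LanA (0.504), LanB2 (0.551) and Ppn (0.505), which were high there, for ND-39 (0.607), which was low, and for its 5 h developmental score (0.526). CG43085 was high in line Drosophila_89 (0.777), Oda (0.668) and Cul1 (0.591) were low in line Drosophila_128, and dco was low in line Drosophila_23 (0.51). Changes from 5 h to 8 h stood apart in line Drosophila_134 for tld (0.531), pros (0.554) and drm (0.524), in line Drosophila_23 for eya (0.543), and in line Drosophila_128 for Ugt35D1 (0.501) and GstE3 (0.654).

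The change from 5 h to 8 h differed among lines by the interaction test of limma in 33 of 148 named genes, against 257 of 18769 probe sets (1.37%). It did in 215 of 6194 measured probe sets, and in 104 of the 1261 measured probe sets called for time. Most named genes were chosen for their change or their line differences, so part of the excess follows from that choice. The first 6 below were chosen by this p, so the count partly restates that choice, and Prosbeta7, bcd and TwdlB were named outside the rule. Adjusted p was 6.4e-09 for Bro, 4e-08 for CG34214, 7.3e-06 for Z600, bard and CG14014, 9e-06 for slam, 9.9e-05 for en, 0.00042 for Prosalpha2 and Elba3, 0.0015 for Sry-alpha and Prosbeta7, 0.0016 for halo, 0.003 for mira, 0.0037 for hry, 0.0048 for eve and 0.0077 for Obp99a and SNCF. It was 0.011 for CG13427, 0.012 for lmd, 0.018 for kni and opa, 0.022 for Drat, 0.025 for Tnpo, 0.027 for ImpL2, 0.028 for TwdlM, 0.03 for CG43085, 0.031 for E(spl)m5-HLH, 0.034 for Prosalpha7, 0.039 for tll and prd, 0.043 for pdm2, and 0.045 for bcd and TwdlB.

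The first pattern weighed is the 3661 probe sets that differed among lines over both times. Line labels drawn again within each time gave at most 54, so 1 of 100 labellings, the real one, gave as many. Scatter between RNA samples alone is thus excluded. The labellings cannot tell a line from the embryo collection that its RNA samples may share. Array brightness as a covariate kept 62.4% of the calls and the developmental score kept 74.6%, while both together kept 1341 calls. Each slope was fitted only from differences between RNA samples of the same line and time, and was carried over to differences between lines. These fits therefore cannot tell how many of the calls either accounts for, and neither is excluded. Mismatch between a line's own sequence and the probes would leave a gene's other probe set unmoved: over 132 genes with another measured probe set, the median correlation of both over 9 lines was 0.46, against 0.0959 as the 95th percentile of random pairs and short of the 0.5 set as the bound before the test. Genetic differences between the lines, brightness, age and mismatch in some genes stay open.

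The second pattern is line Drosophila_75, whose 8 h arrays stayed near the 5 h profile. Embryos as young as those at 5 h would keep cellularisation transcripts, but that list's mean was 4.24 (arrays at 4.18 and 4.3), below the 4.53 to 5.7 of other lines at 5 h, which argues against that, while its own 5 h mean of 4.56 (arrays at 4.51 and 4.6) was already low and a smaller delay stays open. An exchange of its 5 h and 8 h arrays is argued against by its 5 h score of -1.11, below the lowest 8 h score of the other lines, -0.314. Eggs that did not develop, mixed into the collection, may raise maternal transcripts. The maternal list's mean at 8 h was 5.55 in line Drosophila_75 against 4.43 to 5.14 in the others. The 12 genes named for the largest rises over all lines averaged 5.2 there against 5.9 to 7.22 in the others (at 5 h already 4.68 against 4.93 to 6.04). These 12 genes were chosen from the same arrays, line Drosophila_75 included. At 5 h the maternal mean was already 5.61 against 4.71 to 5.5, and a slower loss of maternal transcripts in this genotype stays open and untested. The 8 h arrays of line Drosophila_75 were also the brightest at 8 h (total intensities of 266525 and 212329), and brightness was not tested for this pattern.

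The same labellings gave at most 53 calls at 5 h, 339 at 8 h and 70 for the change that differs among lines, against 1399, 3447 and 257 observed. Exchanging 5 h and 8 h within lines gave at most 188 calls against 1411. In each case 1 of 100, the real one, reached the observed count. A chance labelling of these arrays is thus excluded for time and for lines at 5 h and at 8 h. For the change that differs among lines the draws cannot decide, because they also removed the line differences at each time. For lines the exclusion covers only scatter between RNA samples, which may be technical, and not differences between embryo collections.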

How the results depend on the processing

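Alternatives were chosen before the data were examined, except the 90th-percentile scaling, the pseudocount of 4, the brightness covariate, the negative-control filter, leaving out line Drosophila_75, alone or with line Drosophila_89, the score covariate for the line by time interaction, other scalings of list and single-line counts, and arrays or lines left out of variance shares and list counts, which were chosen after seeing the data. The cause of each move below was not tested unless the setting itself gives it.

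Calls for 8 h against 5 h (1411, with 723 rises and 688 falls) numbered 3276 on the deposited scale (328 and 2948) and 2883 with centred medians (374 and 2509). There were 1349 rises at a common 90th percentile. With arrays as the unit there were 2594 calls (1214 and 1380), and 939 (474 rises) when brightness was added to that fit. By construction there were 636 at adjusted p under 0.01 (365 and 271) and 33 at 2-fold (17 and 16). Calls for lines at 5 h numbered 4418 on the deposited scale, 3191 with centred medians, 486 with brightness, 2267 with array weights, 819 at 0.01 and 509 without lines Drosophila_75 and Drosophila_89. Calls for lines at 8 h were 2243 with the developmental score, 2021 at 0.01 and 2272 without lines Drosophila_75 and Drosophila_89. For lines over both times they were 6259 on the deposited scale, 2323 with brightness, 2394 at 0.01, 483 with a span of 1 and 2075 without both lines. For the line by time interaction they were 152 on the deposited scale, 162 with centred medians, 129 and 153 with pseudocounts of 1 and 4, 414 with the negative-control filter, 68 at 0.01 and 156 without line Drosophila_75.

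The among-line share of variance at 5 h was 20.1% on the deposited scale, 35.5% in the upper part by mean signal and 47.5% with the negative-control filter. The among-line share of variance at 8 h was 22.3%, 34.2% and 43.7% in the same settings, 18.9% with centred medians and 16% at the 90th percentile. Lists called for time went from 18 to 0 with an estimated correlation. Lists that vary among lines went from 13 to 8 with the developmental score, 7 on the deposited scale and 7 with centred medians. Calls for single lines against the other 8, summed, went from 6533 to 14425 on the deposited scale.

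The sample numbers were not taken to pair samples. Between 5 h and 8 h of a line, the differences of sample 1 minus sample 2 correlated across probe sets at -0.389 to 0.279 over 8 lines, with 3 over 0.1. At 5 h the same differences of 8 of 28 pairs of lines correlated over 0.1 (-0.236 to 0.377). With the sample number as a block within each time, a fit over arrays called 2592 probe sets for 8 h against 5 h (1210 rises, 1382 falls). With line by sample number as a random block it called 2664 (1237 and 1427). The sample number as a block gave 1384 for lines at 5 h, 3438 for lines at 8 h, 3612 for lines over both times and 281 for the line by time interaction.

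Leaving out each array gave 1170 to 1587 for 8 h against 5 h (601 to 832 rises, 557 to 762 falls), 1055 to 1656 for lines at 5 h, 2731 to 4023 for lines at 8 h, 3078 to 4126 for lines over both times and 17 to 19 lists. The among-line shares ran from 10.7% to 22.3% at 5 h, the highest without the first 5 h array of line Drosophila_145, and from 9.73% to 18.6% at 8 h. The line by time interaction ran from 144 to 453. It was 170, 157, 144 and 163 without the first 5 h array of lines Drosophila_23, Drosophila_58, Drosophila_75 and Drosophila_83, and 151 and 157 without the second of lines Drosophila_83 and Drosophila_134. It was 154 and 435 without the second 8 h array of lines Drosophila_58 and Drosophila_89, and 403 and 453 without the first of lines Drosophila_83 and Drosophila_128. Leaving out each line gave 918 (without line Drosophila_83) to 1546 for time (494 to 795 rises, 424 to 751 falls) and 2530 to 3680 for lines over both times.

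Over the settings that keep every array, named genes tested for time stayed called in the same direction in 1541 cases, lost the call in 151 and turned in 8. For lines 739 stayed and 11 lost the call, and for the line by time interaction 83 stayed and 1 did not. On the deposited scale wun2 stood at -0.06, RpL37A at -0.01, RpL28 at -0.06 and RpL37-1 at -0.15. With centred medians wun2 stood at -0.04, RpL28 at -0.01 and RpL37-1 at -0.1, and with brightness dhd at 0.18. Signal over background limits dim genes, since 6194 of 18769 probe sets were measured.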

Other observations

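The tests in this part were chosen after seeing the results, except that of the order of genes along chromosomes. Of 26 proteasome subunit genes 16 fell and 0 rose, with a median change of -0.58. The shift had camera p = 9.1e-15, and p = 0.00091 with an estimated correlation, on a list made after the falls were seen. The median was -1.05 on the deposited scale, -1.02 with centred medians and -0.61 at a common 90th percentile. All 12 core genes on this list, which does not hold every core subunit, fell under each of these scalings, among them Prosbeta7 by 0.86 and Prosalpha4 by 0.82. Of 14 regulatory genes 4 fell, among them Rpn12 by 0.68 and Rpt4 by 0.53, and the other 10 were not called, from -0.24 in Rpn13 and Rpt3 to 0.11 in Rpn8. On the deposited scale these 10 stood at -0.6 to -0.17 and 6 of them fell, so that 22 of the 26 genes fell there and with centred medians, and Rpn11, Rpn8, Rpn7 and Rpn1 were not called. At a common 90th percentile 17 of the 26 fell.

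Of 24 Tweedle genes, which encode cuticle proteins, 5 differed among lines over both times by limma, near the 19.5% of all probe sets. They were TwdlB, TwdlN, TwdlL, TwdlM and TwdlD. For time 0 of the 24 were called (9 at an unadjusted p under 0.05; camera p = 0.0012, and p = 0.23 with an estimated correlation). None of the 24 was above the negative-control limit on at least 18 of the 36 arrays. TwdlL at 8 h was 7.67 in line Drosophila_134, 7.07 in line Drosophila_89 and 5.86 in line Drosophila_83, against 4.03 in line Drosophila_23 and 4.06 in line Drosophila_145. TwdlM was 7.27, 6.65 and 6.81 in the same 3 lines and 4.02 in line Drosophila_145.

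Genes that departed in 1 line lay next to a gene departing the same way in 401 adjacent pairs over 9 lines, among 5212 measured genes. Orders drawn at random gave a median of 366 and at most 427 pairs in 1000 draws, a permutation p of 0.03. The lowest permutation p for a single line was 0.08, in line Drosophila_83.

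The 5 h array whose line is not named had a developmental score of -1.27, a total intensity of 104042 and 5399 probe sets above the negative-control limit. Across measured probe sets, which are not independent replicates, it correlated with the 5 h line means at 0.876 in line Drosophila_89 to 0.97 in line Drosophila_23, and at 0.948 in line Drosophila_17.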
